A study of Mus musculus with 16 samples.

How the data were processed

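RNA from bone marrow-derived macrophages of aged C57BL/6 mice was measured by RNA sequencing in 16 libraries, 8 control and 8 beta-glucan, per the labels. RNA was extracted with the RNeasy kit and libraries were made by Novogene, per the labels' protocols. The submitters' processing notes name CASAVA, STAR 2.5, HTSeq 0.6.1, DESeq2 and the genome build mm10. The annotation release, the strand setting of the counting and the enrichment tool are not given in the sources used here.

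The deposited comparison table holds 5 kinds of value. The authors' read counts are whole numbers per gene and library with no normalization. The deposited normalized counts, a signal, equal the read counts divided by 1 size factor per library, between 0.864 and 1.16. The deposited FPKM values equal the normalized counts per kilobase of gene length and scaled to 17937135 reads for every library. The authors' log2 fold change is beta-glucan over control, checked against the libraries. The deposited p-values come unadjusted and with Benjamini-Hochberg adjustment, and adjusted p, rank and p together give 17130 genes tested, with no gap in the ranks. The table thus lists all 3071 genes that passed an adjusted p of 0.05 in the authors' test, and values of the other 14059 genes are not analysed here. The authors' enrichment tables, with p-values and gene counts per term, drew on the 3071 listed genes with no cut at a log2 fold change of 1. Their gene ratios were over 2515 genes for biological processes and 2547 for cellular components. They were over 2483 for molecular functions and 1034 for KEGG.

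Because the counts cover only genes that had already passed, scaling factors computed from them are distorted, and so are spread estimates. The main test therefore departs from the plan in 1 point. edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, filterByExpr, two-sided) was run with the deposited size factors as library sizes in place of TMM, and p was adjusted over 17130 genes. Prior selection makes these tests optimistic, and they measure how clearly each listed gene differs in this sample, not an independent test. Effective library sizes were the size factor times 17937135 reads. No label says that the libraries came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

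Gene lists (18), cell type markers (11 lists) and the rule for named genes were fixed before the data were examined. The rule took the 8 coding genes with the largest rise and the 8 with the largest fall among those past the threshold with at least 5 CPM (edgeR library-scaled counts) in the higher group, without predicted-gene names, and the 4 rising and 4 falling genes with the smallest p. It also took up to 4 members of each list by p, members that did not pass where fewer than 2 passed, and the 2 most abundant listed members of each marker list. Lists with at least 5 tested members were compared with the other listed genes by camera in limma 3.58.1 (correlation 0.01), with an estimated correlation beside it. With the estimated correlation 0 of the 5 camera calls held, 2 lists had an unadjusted p under 0.05, and fry gave an adjusted p under 0.05 for 12 of the 13 lists. The test of fry is against no change, which the selection of the listed genes nearly settles beforehand, so it does not make up for the lost camera calls. Counts adjusted over a list alone are nearly settled in the same way, because the members had already passed in the same data. They are given as a description and not as added support. Listed or called members were compared with all tested genes by Fisher's exact test, two-sided. Benjamini-Hochberg adjustment ran over lists, and over 58 list directions for the called genes. Part of the results of a gene list is not reported here. The lists share some members, so their results are not independent, and members that were not listed may have been untested. Gene types and overlaps came from GENCODE M21. All 3071 gene IDs matched it and 2962 (96.5%) had the same start and end. Coordinates are those of the deposited table.

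The edgeR step was tested on simulated counts for the 3071 genes, of which 2815 passed the filter. It found 52.2% of 67 genes changed by 1.5-fold, 89.6% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, and called 0 unchanged genes. A changed list had a simulated camera p of 7.52e-12 and an unchanged list 0.822. How camera behaves where list members are correlated was not tested by this simulation. Lists called by camera in the real data had estimated correlations from 0.0914 (TCA cycle) to 0.50 (respiratory chain), above the set 0.01. Binomial intervals are exact Clopper-Pearson intervals at 95%, and they cover counting error only. Figures and correlations were made in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

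Alternatives fixed in advance were other size factors, DESeq2 1.42.0, the replicate number as a block, leaving out each library, other filters, thresholds and gene types, and other list statistics. TMM, leaving out controls 12 and 13 or controls 2 and 3, removing a length trend, the estimated correlation and the deposited adjusted p were added after seeing the data.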

Results

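RNA was sequenced from bone marrow-derived macrophages of aged C57BL/6 mice, in 8 control and 8 beta-glucan libraries. Bone marrow cells had been grown for 7 days in 10 ng/mL M-CSF, the growth factor that turns them into macrophages, and then received PBS or 10 µg/mL beta-glucan, a cell wall polysaccharide taken here from the yeast Candida albicans, for 24 hours. They then rested for 7 days, so the RNA reflects macrophages a week after the end of the stimulus and not the acute response. Controls were numbered 2, 3, 5, 7, 9, 10, 12 and 13, and beta-glucan libraries 5, 6, 7, 8, 9, 10, 12 and 13. The deposited table gave counts for 3071 genes, those with the authors' adjusted p under 0.05 among 17130 tested. Reads on these listed genes came to between 4382665 and 5600727 per library. The deposited FPKM and size factors together corresponded to an effective library of 15492864 to 20738976 reads. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 11.8 to 217 over 56 pairs), so none was taken for a repeated deposit of another. Some libraries with neighbouring numbers were the most alike. Control 2 had 12.3 with control 3 and at least 45.8 with the other controls, and control 9 had 11.8 with control 10 and at least 47.2 with the others. Controls 12 and 13 (46.0), beta-glucan 7 and 8 (14.2) and beta-glucan 9 and 10 (17.5) were each other's closest match too. It did not hold for every library, as beta-glucan 12 had 50.6 with 13 but 29.9 with 8. Beta-glucan 6 had 19.5 with 5 but 15.7 with 8. The edgeR tests treat the libraries of a group as independent. Their p-values are too small if such libraries are related, which the labels do not say.

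The comparison of beta-glucan with control asked how training with beta-glucan left the transcriptome of macrophages from aged mice. Beta-glucan libraries had more RNA of the cell cycle inhibitor Cdkn1c, the inhibitory surface glycoprotein Cd200 and the tyrosine kinase Src, and less of the coagulation factor chain F13a1, the scavenger receptor Stab1 and the axon guidance ligand Slit1. The listed genes of the proteasome, the interferon response, the TCA cycle and lipid handling were mostly higher, and those of alternative activation and most listed chromatin modifiers lower. None of the 31 inflammatory cytokine and chemokine genes chosen in advance was among the listed genes. Among the genes of the authors' deposited table, 1079 were higher and 1992 lower, 64.9% of the listed genes. In the edgeR test 2738 of these passed the count filter and 1882 changed, 709 of them higher (median log2 fold change 0.45) and 1173 lower (median -0.67). With a log2 fold change of at least 1 in size, 62 were higher and 333 lower. The 8 control and 8 beta-glucan values did not overlap in 231 listed genes (7.52%), which were chosen because these groups differ. The balance of the directions moved with the scaling. With TMM, computed from the listed genes alone, all log2 fold changes moved up by a median of 0.19 and 1037 genes were higher and 529 lower, so 66.2% of calls were higher against 37.7% with the deposited size factors. Size factors computed anew from the listed genes gave 1055 higher and 517 lower (67.1% higher). Most listed genes were lower, so factors computed from them move the values up by construction. The shift is thus no evidence on the true balance, and the counts with TMM given below carry it too.

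Libraries within a group differed in how far apart they lay. The first principal component held 63.3% of the variance of 2378 listed genes and separated the groups, which the choice of the listed genes by these groups favours. On a scale where the control mean is 0 and the beta-glucan mean 1, controls 12 and 13 lay at 0.574 and 0.501 and the other controls between -0.506 and 0.204, while beta-glucan libraries lay between 0.672 and 1.27. Without controls 12 and 13, 2296 genes changed (866 higher, 1430 lower). Without controls 2 and 3, which had the highest levels of immediate-early genes, 629 changed (184 higher, 445 lower). Leaving out a single library moved the count by over 1.5 times in 4 cases, to 1150 without control 2, 1220 without control 3, 1223 without control 5 and 1206 without beta-glucan 8.

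**Figure D1:**
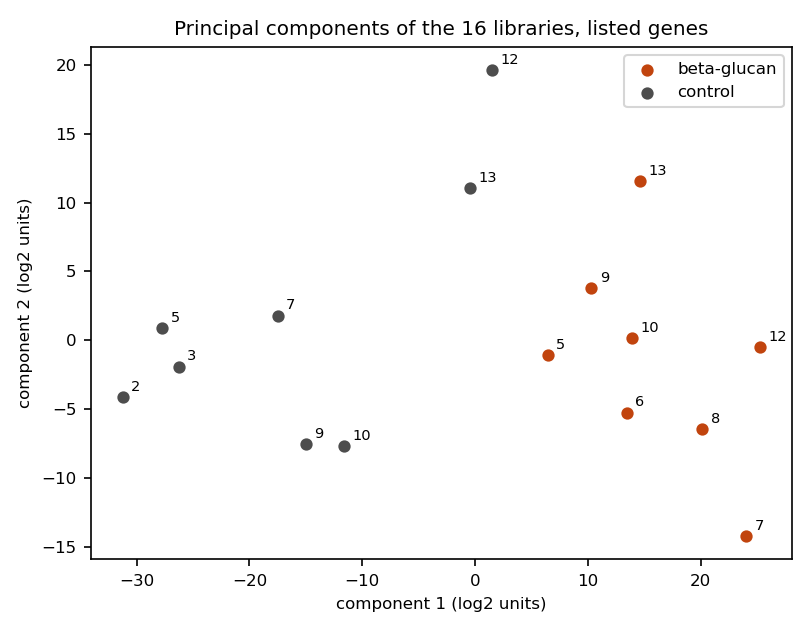
Position of the 16 libraries on the first and second principal components of log2 expression (both axes in log2 units), from 2378 listed genes, with replicate numbers beside the points. Component 1 held 63.3% and component 2 12.4% of the variance, and controls 12 and 13 lay nearest to the beta-glucan libraries.

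The largest rises were in genes of varied function, given here with normalized counts as mean ± SD (n = 8 per group) and with log2 fold changes, always beta-glucan over control, ± SE. Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050, mm10) was at 69.3 ± 60.2 in control and 507 ± 257 with beta-glucan, a change of 2.87 ± 0.44 (adjusted p = 0.00120). Its beta-glucan values ranged from 262 to 1075. Cd200 (ENSMUSG00000022661, chromosome 16, 45382135 to 45409053) was at 82.9 ± 62.6 in control and 465 ± 59.2 with beta-glucan (2.48 ± 0.39, adjusted p = 0.00129). Src (ENSMUSG00000027646, chromosome 2, 157418444 to 157471862), a kinase that acts in adhesion and bone resorption, was at 154 ± 64.2 in control and 547 ± 136 with beta-glucan (1.83 ± 0.24, adjusted p = 0.000483). The other large rises were H2-M2 (2.79 ± 0.42, adjusted p = 0.00120), Mgll (2.46 ± 0.43, adjusted p = 0.00238), Dio2 (2.46 ± 0.51, adjusted p = 0.00552), Pdpn (2.06 ± 0.32, adjusted p = 0.00134) and Dach1 (1.71 ± 0.29, adjusted p = 0.00191). H2-M2 is a class Ib MHC gene with close paralogs, so its count is uncertain. Mgll encodes monoacylglycerol lipase, Dio2 the deiodinase that activates thyroid hormone and Pdpn the membrane glycoprotein podoplanin. Among the rising genes with the smallest p, the monoamine oxidase Maoa (ENSMUSG00000025037, chromosome X, 16619698 to 16687818) was at 1091 ± 156 in control and 2006 ± 302 with beta-glucan (0.88 ± 0.11, adjusted p = 0.000166), followed by Plpp3 (1.40 ± 0.17, adjusted p = 0.000187) and Vopp1 (0.81 ± 0.11, adjusted p = 0.000838).

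F13a1 (ENSMUSG00000039109, chromosome 13, 36867178 to 37050244, mm10), the A chain of coagulation factor XIII and a marker of monocytes, had the largest fall, with 345 ± 182 in control and 27.1 ± 10.2 with beta-glucan normalized counts (-3.66 ± 0.42, adjusted p = 0.000163; mean ± SD, n = 8 per group). Controls 12 and 13 had 61.5 and 74.4 counts of F13a1 and the other controls between 312 and 520. Slit1 (ENSMUSG00000025020, chromosome 19, 41600257 to 41743665) was at 419 ± 142 in control and 122 ± 21.9 with beta-glucan (-1.77 ± 0.19, adjusted p = 0.000163). Stab1 (ENSMUSG00000042286, chromosome 14, 31139013 to 31168641), one of the most abundant transcripts listed, was at 67255 ± 21130.4 in control and 23277 ± 3285 with beta-glucan (-1.53 ± 0.18, adjusted p = 0.000163). The receptor of the granulocyte growth factor G-CSF, Csf3r (ENSMUSG00000028859, chromosome 4, 126024550 to 126044440), was at 2163 ± 244 in control and 1141 ± 188 with beta-glucan (-0.92 ± 0.10, adjusted p = 0.000163). Further large falls were P2ry12 (-2.02 ± 0.34, adjusted p = 0.00181) and Adgb (-1.96 ± 0.32, adjusted p = 0.00151), where P2ry12 is a purinergic receptor, and that of the growth factor midkine, Mdk, at 102 ± 57.2 in control and 25.3 ± 13.7 with beta-glucan (adjusted p = 0.00413).

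**Figure D2:**
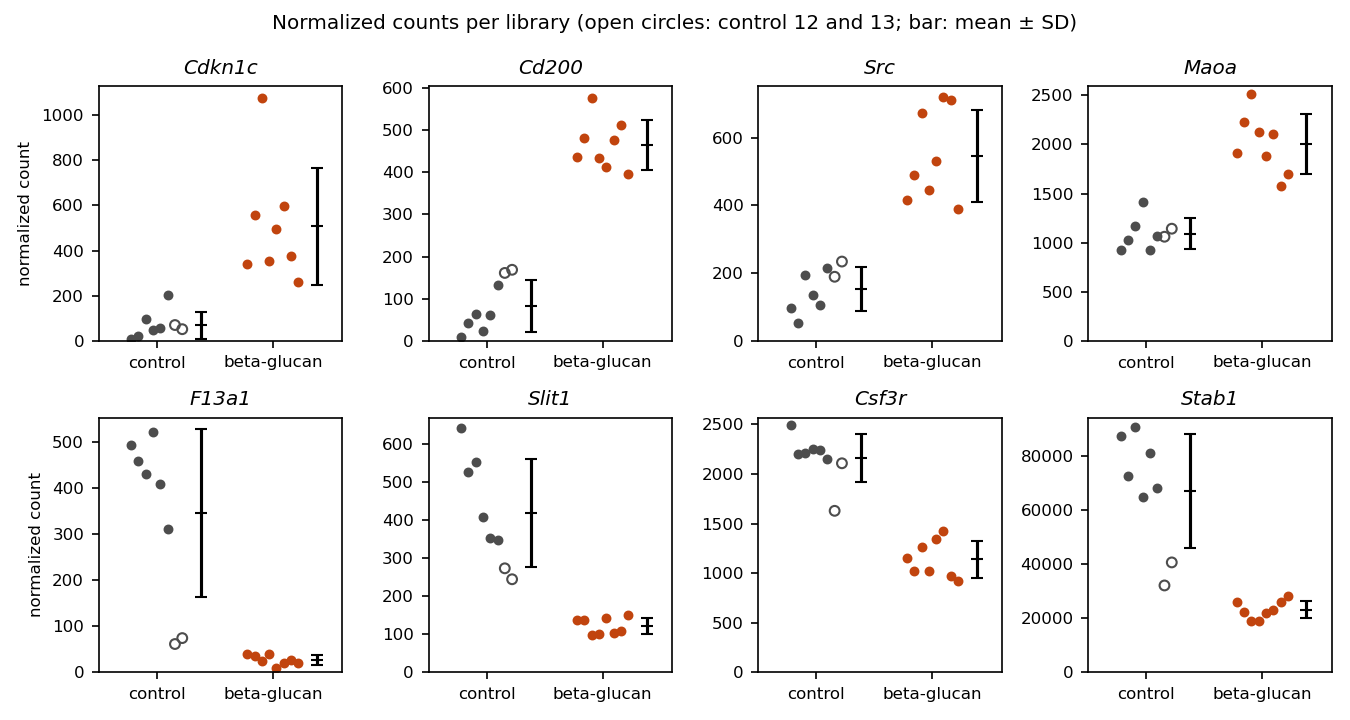
Normalized counts (vertical axis, linear from 0) of 4 genes that rose and 4 that fell, 1 point per library, with bars for the mean ± SD of 8 libraries per group. F13a1 averaged 345 in control and 27.1 with beta-glucan, and open circles mark controls 12 and 13, which lie nearer the beta-glucan libraries in Stab1 and F13a1.

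A second set of large falls came from immediate-early genes, which cells switch on within minutes to hours of a stimulus, and from the matrix gene Fn1. These were Fosb (-2.22 ± 0.53, adjusted p = 0.0120), Nfkbiz (-2.17 ± 0.52, adjusted p = 0.0123), Kdm6b (-1.95 ± 0.52, adjusted p = 0.0218) and Fn1 (-1.89 ± 0.60, adjusted p = 0.0470), where Fosb is an AP-1 transcription factor, Nfkbiz a nuclear IkappaB protein and Kdm6b a histone demethylase. The control means rested on few libraries. Fosb had 1746 normalized counts in control 2 and 1329 in control 3, against 125 to 760 in the other controls and 17.9 to 247 with beta-glucan. None of these 4 genes passed in the fit without controls 2 and 3, with log2 fold changes of -1.34 for Fosb (adjusted p = 0.0930), -0.96 for Nfkbiz (0.0968), -0.83 for Kdm6b (0.227) and -0.79 for Fn1 (0.819). The replicate block over 12 libraries also lacks these controls, and there Nfkbiz passed (-0.98, edgeR adjusted p = 0.0314). Fosb (0.101), Kdm6b (0.144) and Fn1 (0.516) did not. The gene Kdm6b already missed the threshold without control 2 alone (-1.40, adjusted p = 0.0623) or control 3 alone (-1.73), and Fn1 in 12 of the 16 fits that left out 1 library.

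Of the 32 interferon-stimulated genes, which cells express in answer to interferon, 10 were listed higher and 1 lower in the authors' deposited table. The 11 listed, against 5.74 expected, were not shown to be more than among all tested genes (Fisher's exact test, adjusted p = 0.123). In edgeR 7 rose and none fell. Adjusted over the list alone, 11 passed, which here and in the lists below is nearly settled by the earlier selection and no added support. Examples were Ifit2 (0.56 ± 0.13, adjusted p = 0.00877), Rsad2 (0.71 ± 0.16, adjusted p = 0.0109), Ifit1 (0.51 ± 0.15, adjusted p = 0.0317) and Cmpk2 (0.88 ± 0.26, adjusted p = 0.0348). Ifit2 was at 352 ± 53.5 in control and 519.8 ± 98.9 with beta-glucan normalized counts, and Oas2 was the listed member with a negative value, -0.77 ± 0.25 (adjusted p = 0.0516). The rising genes were more frequent than among all genes tested (Fisher's exact test, adjusted p = 0.00531, a call that ended without controls 2 and 3), and the listed members lay above the other listed genes (camera, adjusted p = 0.00648; adjusted p = 0.299 with an estimated correlation). Only 1 member rose without controls 2 and 3, where the median log2 fold change of the listed members was 0.54 against 0.56 and 9 rose at an unadjusted p under 0.05. With each library's gene length trend removed 3 rose (median 0.38), and the calls of Ifit1 and Cmpk2 ended in 8 and 9 of the 16 fits without 1 library. The mean log2 level of the listed members, centred over all libraries, was 0.198 in control 12 and 0.286 in control 13. Both lay within the beta-glucan range of 0.0172 to 0.707, of which beta-glucan 13 was the highest. The other controls lay between -0.727 and -0.0815.

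The listed energy metabolism genes were mostly higher. Of 25 genes of the TCA cycle and glutamine use, 6 were listed, near the 4.48 expected (Fisher's exact test, adjusted p = 0.660). All 6 rose in edgeR and also when adjusted over the list alone. The rising genes were more frequent than among all genes tested (Fisher's exact test, adjusted p = 0.00643, a call that ended without controls 2 and 3). By camera the adjusted p was 0.0140, and 0.299 with an estimated correlation. The 6 genes included Dld (0.34 ± 0.07, adjusted p = 0.00650), Acod1 (1.25 ± 0.31, adjusted p = 0.0140), Sucla2 (0.37 ± 0.09, adjusted p = 0.0148) and Cs (0.26 ± 0.07, adjusted p = 0.0294). Acod1 makes itaconate, an immune metabolite, and is not a step of the cycle itself. Of 37 respiratory chain genes, 11 were listed, all higher; 4 rose in edgeR and 11 when adjusted over the list alone (camera, adjusted p = 0.00576, and adjusted p = 0.299 with an estimated correlation; Fisher's exact test, adjusted p = 0.316). Their 4 calls were Ndufa9 (0.46 ± 0.10, adjusted p = 0.00842), Ndufv1 (0.37 ± 0.09, adjusted p = 0.0142), Uqcrc2 (0.24 ± 0.08, adjusted p = 0.0473) and Atp5b (0.24 ± 0.08, adjusted p = 0.0496). Of 23 glycolysis genes, 6 were listed higher and 2 lower, and 4 rose and 1 fell in edgeR, 8 changing when adjusted over the list alone (camera, adjusted p = 0.0805). The lactate transporter gene Slc16a1 rose (0.51 ± 0.10, adjusted p = 0.00501), as did Pgam1 (0.30 ± 0.08, adjusted p = 0.0215) and Tpi1 (0.43 ± 0.13, adjusted p = 0.0330), while Pfkm fell (-0.49 ± 0.11, adjusted p = 0.00909). In each of the 3 lists 1 gene rose without controls 2 and 3, with medians of the listed members of 0.33 (TCA cycle), 0.28 (respiratory chain) and 0.28 (glycolysis), each against 0.36 in the full fit. With the length trend removed 1 respiratory chain and 1 glycolysis gene rose, and with TMM all 11 listed respiratory chain genes. The calls of Cs, Tpi1, Uqcrc2 and Atp5b ended in 7, 10, 12 and 13 of the 16 fits without 1 library.

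The listed lipid handling genes mostly rose. Of 30 genes of lipid handling and cholesterol efflux, 7 were listed higher and 2 lower, and 7 rose and 1 fell in edgeR, 9 changing when adjusted over the list alone (camera, adjusted p = 0.0140, and adjusted p = 0.299 with an estimated correlation; Fisher's exact test for the rises, adjusted p = 0.00518, a call that ended without controls 2 and 3). The 9 listed, against 5.38 expected, were not shown to be more than among all tested genes (Fisher's exact test, adjusted p = 0.249). The sterol-sensing receptor Nr1h3 (LXR alpha), the cholesterol exporter Abcg1, the lipid chaperone Fabp5 and the glycoprotein Gpnmb rose, as Nr1h3 (0.73 ± 0.15, adjusted p = 0.00520), Abcg1 (0.85 ± 0.18, adjusted p = 0.00569), Fabp5 (0.80 ± 0.18, adjusted p = 0.0106) and Gpnmb (0.37 ± 0.08, adjusted p = 0.00927). Abcg1 is a target of Nr1h3, but so are Lpcat3, the gene of the list that fell (-0.37 ± 0.10, adjusted p = 0.0265), and Apoe, with a negative value that did not pass (-0.68 ± 0.22, adjusted p = 0.0504), both named after their values were seen. Gpnmb was among the most abundant transcripts listed, at 250382 ± 30871 in control and 323501 ± 22869 with beta-glucan normalized counts. Of the lipid handling genes, 3 rose without controls 2 and 3 (median log2 fold change of those listed 0.64 against 0.73). Of the cholesterol synthesis and uptake genes, Fdps fell (-0.86 ± 0.26, adjusted p = 0.0387), a call that ended with TMM, where its unadjusted p was still under 0.05, and in 10 of the 16 fits without 1 library.

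The proteasome, which degrades tagged proteins, was the strongest term in the authors' deposited enrichment tables, which tested the listed genes. There, 17 genes of the proteasome accessory complex were higher and none lower (70.8% of the term's background genes against 17.3% of all, adjusted p = 5.79e-06). The related terms were the proteasome regulatory particle (16 higher, 0 lower), its base subcomplex (9 higher, 0 lower), the proteasome complex (28 higher, 0 lower, adjusted p = 7.55e-05), the endopeptidase complex and the peptidase complex. KEGG's Proteasome had 22 higher and none lower (adjusted p = 0.000492) and was the only KEGG pathway of 306 past 0.05 there. Among the 24 listed genes with Psm symbols, a set chosen after its values were seen, all 24 had positive values and 18 rose in edgeR (median log2 fold change 0.36). The largest were Psmd8 (0.65 ± 0.12, adjusted p = 0.00250) and Psmb5 (0.64 ± 0.13, adjusted p = 0.00420), with Psmd8 at 3987 ± 809 in control and 6253 ± 726 with beta-glucan normalized counts (n = 8 per group). Of the 24, 7 rose without controls 2 and 3 and 23 at an unadjusted p under 0.05 there, with a median of 0.35.

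Counting the proteasome terms, 15 of 710 cellular components and 4 of 1011 molecular functions were past 0.05 in the authors' deposited tables, and 0 of 5681 biological processes. The smallest adjusted p of a biological process was 0.114, for intracellular steroid hormone receptor signaling, steroid hormone mediated signaling and androgen receptor signaling. Carbohydrate catabolism and hormone-mediated signaling followed (0.151). Higher in the authors' table were genes of the preribosome (28 higher, 0 lower, adjusted p = 0.00432), the small-subunit processome (15 higher, 0 lower) and translation factors (23 higher, 4 lower, adjusted p = 0.0266). Both directions occurred in the nuclear envelope (45 higher, 46 lower), fibrillar center (18 and 18), nucleolar part (31 and 19), ruffle (15 and 24) and leading edge membrane (14 and 21). Lower for the most part were GTPase activators (14 higher, 51 lower, adjusted p = 0.00295), the overlapping GTPase and nucleoside-triphosphatase regulators, the clathrin-coated pit (7 higher, 18 lower, adjusted p = 0.000798) and receptor complexes (17 higher, 52 lower, adjusted p = 0.0395). Mannosidase activity had 0 higher and 9 lower (adjusted p = 0.0513). In KEGG, ferroptosis, the lysosome and Epstein-Barr virus infection had an adjusted p = 0.0943 in the authors' table and ribosome biogenesis and other glycan degradation 0.197. Hepatitis C, PI3K-Akt signaling, fluid shear stress and inflammatory mediator regulation of TRP channels had 0.248.

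Of the 28 genes of pattern recognition and beta-glucan signalling, 3 were listed higher and 10 lower, against 5.02 expected in both directions (Fisher's exact test, adjusted p = 0.00913). In edgeR 3 rose and 7 fell, and 13 changed when adjusted over the list alone. The fall was more frequent than among all genes tested (Fisher's exact test, adjusted p = 0.0222, a call that ended without controls 2 and 3), and the listed members were not shown to differ from the other listed genes (camera, adjusted p = 0.313). The DNA-sensing receptor Tlr9 and the peptidoglycan sensor Nod1 fell, Tlr9 (-1.19 ± 0.21, adjusted p = 0.00242) and Nod1 (-0.66 ± 0.13, adjusted p = 0.00435), as did the mannose receptor Mrc1 (-0.80 ± 0.16, adjusted p = 0.00418). The C-type lectin Clec4e (Mincle) rose (1.06 ± 0.20, adjusted p = 0.00388), as did Clec7a, which encodes the beta-glucan receptor Dectin-1 (0.84 ± 0.22, adjusted p = 0.0210) and was singled out after its value was seen. In the fit without controls 2 and 3, 1 member rose and 4 fell (median log2 fold change of those listed -0.43 against -0.50), and with TMM 3 rose and 4 fell. With the replicate block over 12 libraries, Tlr9 (edgeR adjusted p = 0.0625), Nod1 (0.0589), Mrc1 (0.0942) and Clec4e (0.0684) did not pass.

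The listed alternative activation genes, which macrophages express under IL-4 or in resident tissue states, moved one way. Of 23 genes, 7 were listed, and all 7 fell in edgeR and also when adjusted over the list alone (camera, adjusted p = 0.0171, and adjusted p = 0.299 with an estimated correlation; Fisher's exact test for the falls, adjusted p = 0.00745, a call that ended without controls 2 and 3). The 7 listed, against 4.12 expected, were not shown to be more than among all tested genes (Fisher's exact test, adjusted p = 0.371). The scavenger receptor Cd163 fell, at 259 ± 103 in control and 88.2 ± 28.1 with beta-glucan (-1.55 ± 0.25, adjusted p = 0.00152), and the lectin Clec10a by a similar amount (-1.20 ± 0.26, adjusted p = 0.00798), beside Stab1 and Mrc1. With TMM 4 fell, and without controls 2 and 3, 3 fell (median log2 fold change -0.79 against -1.20). In Stab1 controls 12 and 13 had 32173 and 40701 normalized counts, between the beta-glucan maximum of 28239 and the other controls, which started at 64963.

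The listed chromatin modifiers were mostly lower. Of 32, 2 were listed higher and 12 lower, more than the 5.74 expected (Fisher's exact test, adjusted p = 0.00913), and 2 rose and 11 fell in edgeR, 14 changing when adjusted over the list alone. The falls were more frequent than among all genes tested (Fisher's exact test, adjusted p = 0.000290, a call that ended without controls 2 and 3), and the listed members were not shown to differ from other listed genes (camera, adjusted p = 0.158). The DNA demethylase Tet2 was at 767 ± 244 in control and 319 ± 96.4 with beta-glucan normalized counts (-1.26 ± 0.21, adjusted p = 0.00171), the histone methyltransferase Kmt2b fell (-0.69 ± 0.18, adjusted p = 0.0173) and the deacetylase Hdac2 rose (0.37 ± 0.10, adjusted p = 0.0178). With TMM only 2 fell, and with each library's gene length trend removed 3 fell. In the fit without controls 2 and 3, 2 fell (median log2 fold change of those listed -0.43 against -0.48).

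Among lysosome and phagosome genes both directions occurred. Of 33, 7 were listed higher and 4 lower, and 5 rose and 4 fell in edgeR, 10 changing when adjusted over the list alone (camera, adjusted p = 0.112). The alpha-galactosidase Gla (0.60 ± 0.11, adjusted p = 0.00250), the protease Ctsz (0.46 ± 0.08, adjusted p = 0.00294) and the proton pump subunit Atp6v1b2 (0.53 ± 0.12, adjusted p = 0.0107) rose, and the beta-galactosidase Glb1 fell (-0.50 ± 0.10, adjusted p = 0.00365). With TMM 7 rose and 1 fell, and without controls 2 and 3, 2 rose and 1 fell (median of those listed 0.32 against 0.34). With the length trend removed the call of Ctsz ended (0.16, edgeR adjusted p = 0.245), while those of Gla, Atp6v1b2 and Glb1 held. Of 27 matrix and adhesion genes, 2 were listed higher and 7 lower, and 2 rose and 6 fell in edgeR, 8 changing when adjusted over the list alone (camera, adjusted p = 0.313). The collagenase Mmp8 (-1.37 ± 0.22, adjusted p = 0.00159), the integrin Itga6 (-0.96 ± 0.16, adjusted p = 0.00182) and Tgfbi (-1.20 ± 0.23, adjusted p = 0.00413) fell, while the hyaluronan receptor Cd44 rose (0.46 ± 0.10, adjusted p = 0.00803). Fewer changed without controls 2 and 3, with 2 rising and 3 falling (median of those listed -0.68 against -0.90).

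Some stress genes changed. Of 24 integrated stress response and amino acid supply genes, 4 were listed higher and 1 lower, and 4 rose in edgeR and when adjusted over the list alone (camera, adjusted p = 0.0805): Trib3 (0.87 ± 0.21, adjusted p = 0.0146), Wars (0.32 ± 0.08, adjusted p = 0.0151), Atf3 (0.58 ± 0.16, adjusted p = 0.0245) and Slc7a11 (1.18 ± 0.37, adjusted p = 0.0477). By the edgeR test 0 rose without controls 2 and 3 (4 at an unadjusted p under 0.05; median log2 fold change of those listed 0.44 against 0.58), and 1 with the length trend removed. The gene Atf3 missed the threshold without control 2 (adjusted p = 0.0530) or control 5 (0.0518), and Slc7a11 in 12 of the 16 fits without 1 library. Of 24 oxidative stress genes, 4 were listed higher and 4 lower, and in edgeR 2 rose and 1 fell, 8 changing when adjusted over the list alone (camera, adjusted p = 0.396). The sulfiredoxin Srxn1 rose (0.53 ± 0.13, adjusted p = 0.0123), as did Slc7a11, the cystine carrier, which is in both lists. Gclc, of glutathione synthesis, fell (-0.48 ± 0.15, adjusted p = 0.0432), a call that ended in 13 of the 16 fits without 1 library. Without controls 2 and 3, none of Srxn1 (0.50, edgeR adjusted p = 0.0598), Slc7a11 (1.01, 0.185) and Gclc (-0.47, 0.130) passed. With the length trend removed the call of Srxn1 ended (adjusted p = 0.0828), while those of Slc7a11 and Gclc held.

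Antigen presentation, cell cycle and senescence genes had at most 2 calls in a list. Of 16 MHC class II genes 1 was listed higher and 2 lower, and the costimulatory ligand Cd86 fell (-0.83 ± 0.21, adjusted p = 0.0171), the only call also when adjusted over the list alone, while Cd74 was at 0.72 ± 0.26 (adjusted p = 0.0738). Of 20 MHC class I genes 2 were listed higher and 1 lower: the transactivator Nlrc5 fell (-0.64 ± 0.17, adjusted p = 0.0248) and H2-Q6, which has close paralogs and is uncertain, rose (0.93 ± 0.29, adjusted p = 0.0428), 2 changes also when adjusted over the list alone. The call of H2-Q6 ended in 10 of the 16 fits without 1 library, and the gene Nlrc5 missed the threshold without control 5 (adjusted p = 0.0548) or beta-glucan 8 (0.0536). Without controls 2 and 3, none of Cd86 (-0.64, edgeR adjusted p = 0.0985), Nlrc5 (-0.68, 0.0568) and H2-Q6 (1.01, 0.0890) passed. Of 32 cell cycle genes 1 was listed higher and 2 lower. In edgeR 0 of these 3 passed, also when adjusted over the list alone, although all 3 are past the threshold in the authors' deposited table and had an unadjusted edgeR p under 0.05: Ccne2 (0.57 ± 0.19, adjusted p = 0.0659), Cenpf (-0.50 ± 0.17, adjusted p = 0.0719) and Mki67 (-0.53 ± 0.20, adjusted p = 0.0991). Of 21 senescence genes 2 were listed higher and 3 lower, and 2 fell in edgeR, Glb1 and Igfbp4 (-0.42 ± 0.13, adjusted p = 0.0435), with 4 changes when adjusted over the list alone. The call of Igfbp4 ended in 12 of the 16 fits without 1 library.

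None of the 31 inflammatory cytokine and chemokine genes was listed, against 5.56 expected if they were like all tested genes (Fisher's exact test, adjusted p = 0.0363). Any member too low to have been tested would make this depletion weaker, and the table does not show which were. The authors' deposited table therefore holds no measured change for this list, which includes the tumour necrosis factor gene Tnf and the interleukin gene Il6.

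Markers of cell types gave a mixed picture. Of 15 macrophage markers 1 was listed higher and 6 lower, and 1 rose and 4 fell in edgeR, 7 changing when adjusted over the list alone (camera, adjusted p = 0.178); the M-CSF receptor Csf1r was at 70874 ± 16817 in control and 44301 ± 3192 with beta-glucan normalized counts (-0.68 ± 0.12, adjusted p = 0.00276) and Adgre1, which encodes F4/80, fell (-0.56 ± 0.10, adjusted p = 0.00250). Both listed monocyte markers had negative values, F13a1 and Cx3cr1 (-1.42 ± 0.46, adjusted p = 0.0510), of which F13a1 passed. Both listed neutrophil markers fell, Csf3r and Mmp8. Both listed osteoclast markers rose, Atp6v0d2 (1.36 ± 0.41, adjusted p = 0.0383) and Itgb3 (0.80 ± 0.19, adjusted p = 0.0107), although the call of Atp6v0d2 ended in 13 of the 16 fits without 1 library. Of 9 B cell markers 2 were listed, the heavy chain gene Ighm fell (-1.25 ± 0.20, adjusted p = 0.00148) and Cd79b did not pass (-0.89 ± 0.30, adjusted p = 0.0610). The listed fibroblast markers Acta2 and Sparc (adjusted p = 0.110 and 0.195) and the endothelial markers Vwf and Kdr (adjusted p = 0.0748 and 0.103) did not pass in edgeR, although each had an unadjusted p under 0.05 and is past the threshold in the authors' table. No dendritic cell, T or NK cell, mast cell or basophil, or erythroid or megakaryocyte marker was listed.

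The direction of change also went with gene length and type. Of 385 listed noncoding RNA genes, 377 were lower with beta-glucan (97.9%), against 1535 of 2580 coding genes (59.5%). Antisense and sense genes cannot be separated where counting ignores strand, and the strand setting is not given in the sources used here. In edgeR 202 of the noncoding genes were tested, of which 2 rose and 129 fell (median log2 fold change -1.40). With TMM 4 rose and 77 fell, and without controls 2 and 3, 2 rose and 46 fell (median -1.28). Among coding genes split by length into 5 groups of about equal size, 32.7%, 43.5%, 57.4%, 73.3% and 90.7% were lower from the shortest to the longest. The median length was 3405 bases for coding genes that were higher and 6216 for those that were lower. With each library's length trend removed, 1472 genes changed, 499 higher and 973 lower.

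**Figure D3:**
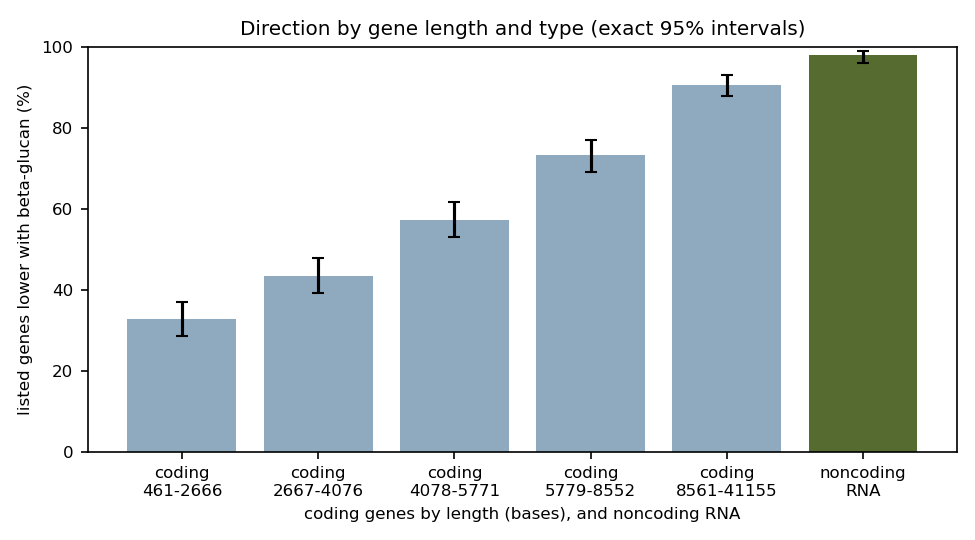
Percent of listed genes that were lower with beta-glucan (vertical axis), for coding genes in 5 groups of gene length in bases and for noncoding RNA, with exact 95% binomial intervals as error bars. The percent is 32.7% in the shortest coding genes, 90.7% in the longest and 97.9% in noncoding RNA.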

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

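All tests on controls 12 and 13 were chosen only after the results were seen. In 188 groups of 8 values, from the named genes and summary measures of the libraries, 12 had 1 library far from the others by the size of its gap, where chance gives about 9.4, so the number itself is unremarkable. Values are normalized counts.

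Among beta-glucan libraries, replicate 7 had 1075 of Cdkn1c against 262 to 596 in the others, 79.9 of Acta2 against at most 43.3 and 81.0 of Sparc against 0 to 25.3. Replicate 12 had 1285 of Itgb3 against 898 to 1038 and 867 of Rsad2 against 623 to 736. Replicate 13 had 29.6 of Cd79b against 5.50 to 15.7. Among controls, replicate 10 had 201 of Cdkn1c against 6.95 to 98.5 and 419 of Mgll against 44.7 to 189. Control 12 had 1629 of Csf3r against 2109 to 2492 and 1127 of Ndufv1 against 872 to 975. Control 2 had 30.1 of Kdr against 66.0 to 87.4, and control 5 had 899 of Nlrc5 against 447 to 599.

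Controls 12 and 13 lay near the beta-glucan libraries, at 0.574 and 0.501 on the scale from control to beta-glucan. An exchange between the groups and beta-glucan cultures labelled as control cannot be told apart from true controls here, because the listed genes were chosen with the labelled groups, which favours each library's own side. The lowest beta-glucan library lay at 0.672, and control 12 lay beyond the beta-glucan range on the control side in 41.2% of listed genes and control 13 in 46.5%, against at most 26.0% for a left-out beta-glucan library. A shared day or batch with beta-glucan 12 and 13 may contribute, since the deviations of these pairs correlated at 0.370, the highest of 28 pairs of beta-glucan libraries (next 0.189), although the labels give no batch. A biological difference between the cultures was not tested and stays open.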

How the results depend on the processing

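The count named genes changed, beta-glucan against control, 1882 (709 higher, 1173 lower), stayed within 1.5 times with no filter (2214), a mean of at least 50 (1532), coding genes alone (1620), the length trend removed (1472), an adjusted p of 0.1 (2675) and without controls 12 and 13 (2296). The split moved with TMM (529 lower) and with size factors from the listed genes (517 lower). Both were computed from genes of which 64.9% were lower, so they moved the log2 fold changes up by construction (medians 0.19 and 0.20). Thresholds moved counts by construction: an adjusted p of 0.01 left 548 (156 higher, 392 lower) and a log2 fold change of 1 left 395 (62 higher, 333 lower). Adjusting over the listed genes alone, which counts fewer tests, gave 1069 for genes changed, beta-glucan against control, higher. Centring on the listed median gave 770 higher and 1112 lower. DESeq2 called 2942 (1886 lower), and the authors' adjusted p all 3071 (1079 higher, 1992 lower), since it selected the table. Without controls 2 and 3, 629 changed (184 higher, 445 lower); the cause was not tested, and fewer samples also lower the power.

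Fits without 1 library gave 1150 (without control 2) to 2276 (without control 12) genes, 381 to 871 higher and 769 to 1405 lower. The 6 list directions called by Fisher's exact test ranged from 2 to 10 in these fits. They were 11 without controls 12 and 13, and 0 without controls 2 and 3 (7 at an unadjusted Fisher p under 0.05). The cause was not tested.

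Whether replicate numbers mark pairs is not settled. Of 6 shared numbers, 1 correlated best with its own number, while beta-glucan 12 correlated best with control 13 and beta-glucan 13 with control 12. Correlations of same-numbered libraries were 0.54, 0.02, -0.06, 0.01, 0.20 and 0.37 for numbers 5, 7, 9, 10, 12 and 13. The replicate block over these 12 libraries called 355 genes (111 higher, 244 lower) and 2 list directions; without the block the same libraries gave 68 (24 higher, 44 lower) and 0 list directions (4 at an unadjusted Fisher p under 0.05), where the log2 fold change of the gene Sparc turned to 0.14. The cause was not tested.

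The camera count of 5 lists fell to 0 with an estimated correlation, which allows for the correlation between members by construction. The list glycolysis (adjusted p = 0.0476) and the list integrated stress response and amino acid supply (0.0476) passed with no filter, the latter also with the block (0.0213) and with ranks (0.0411), and the list lysosome and phagosome (0.0481) with shared members left out. For named genes, 1951 results across settings kept their direction and side of the threshold, 325 no longer passed and 39 newly passed. Of 76 named genes that changed, 59 did so in every fit without 1 library, 43 without controls 2 and 3, 36 with the block and 68 with TMM. The 20 enrichment terms became 12 at an adjusted p of 0.01 by construction. A list overlap with a background of genes of a mean of at least 50 was not run, because their number among all tested genes is not known here. In the simulation 52.2% of 1.5-fold changes were found. With few changed genes its threshold was stricter than that of the real fit, where Atp5b passed at a log2 fold change of 0.24, so this share is not the limit of the real fit.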

Other observations

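The tests in this part, on the clock genes, gene length, introns, library variation, immediate-early genes and splits, were all chosen only after the results were seen. Several genes of the circadian clock were lower with beta-glucan. Of 19 clock genes, 9 were listed, 7 lower and 2 higher, against 3.41 expected (Fisher's exact test, two-sided, p = 0.00308). Since the set was chosen after the results were seen, this p is not independent support. In edgeR Per3 (-1.44 ± 0.22, adjusted p = 0.00120), Dbp (-0.85 ± 0.15, adjusted p = 0.00255), Nr1d1 (-1.03 ± 0.26, adjusted p = 0.0170), Per1 (-1.19 ± 0.29, adjusted p = 0.0132), Tef (-0.43 ± 0.12, adjusted p = 0.0257) and Arntl (-0.44 ± 0.13, adjusted p = 0.0352) fell (n = 8 per group). Bhlhe41 (0.65 ± 0.22, adjusted p = 0.0639) and Cry1 (0.41 ± 0.15, adjusted p = 0.0819) had positive values and did not pass. Normalized counts of Per1 varied widely in control (1282 ± 857, against 562 ± 58.5 with beta-glucan), and those of Tef less (2257 ± 388 against 1671 ± 267). The dependence of the clock genes on controls 2 and 3 is not given here. Arntl and Per3, whose levels peak at different hours in a running clock, both fell, and the hour of harvest is not given in the sources used here.

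Some further sets were noticed among the listed genes, which does not show a change of the whole set. All 14 listed genes with Mrp symbols, of the mitochondrial ribosome, had positive values and 7 rose (median log2 fold change 0.42). With TMM, which moved the log2 fold changes up by construction, all 14 rose. Without controls 2 and 3, 1 did, with 12 at an unadjusted p under 0.05 and a median of 0.39. All 8 listed mannosidase genes with Man symbols had negative values and 6 fell (median -0.41), against 2 with TMM and 3 without controls 2 and 3 (median -0.40).

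Listed long coding genes and noncoding RNAs were mostly lower with beta-glucan and listed short coding genes mostly higher. The tables argue against a gene length bias as the whole cause for the noncoding RNAs. Those shorter than the median rising coding gene were lower in 97.9% of cases, against 34.7% of coding genes of the same lengths. The median of the proteasome genes went from 0.36 to 0.27, with 13 of 18 calls left, once a length trend fitted on the listed genes was removed. This does not decide on a length bias for the proteasome genes. They were chosen after their values were seen, and the trend came from the same listed genes. Reads from introns of coding genes would not reach noncoding RNAs outside every coding gene, of which 93 of 97 were lower (95.9%, interval 89.8% to 98.9%). This covers only those 97 of the 385 listed noncoding RNAs. For the 120 that overlap a coding gene on the same strand and the 168 on the opposite strand only, such reads stay open. For long coding genes a length bias cannot be told apart from the treatment, since the trend was fitted on the same listed genes. It left the listed lysine methyltransferases with Kmt symbols, which are not all of that class, at a median of -0.30 against -0.69. Variation between libraries other than the treatment may contribute. Controls with more noncoding RNA had less proteasome RNA, with Pearson's r = -0.815 (exact permutation p = 0.00749, adjusted 0.00999, Spearman's rho -0.810, exact permutation p = 0.0218, adjusted 0.0436, r = -0.659 without the 2 farthest). In beta-glucan libraries this relation did not pass, with r = -0.708 (exact permutation p = 0.0502, adjusted 0.0502, rho -0.714, exact permutation p = 0.0576, adjusted 0.0576, r = -0.609 without 2). Controls with more RNA of long coding genes had less proteasome RNA too, with r = -0.972 (exact permutation p = 0.000347, adjusted 0.00139, rho -0.833, exact permutation p = 0.0154, adjusted 0.0436, r = -0.879 without 2). In beta-glucan libraries r was -0.859 (exact permutation p = 0.00667, adjusted 0.00999, rho -0.738, exact permutation p = 0.0458, adjusted 0.0576, r = -0.742 without 2), so after adjustment only Pearson's r passed there. In all, 4 relations were tested, and an effect of the treatment itself stays open.

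Immediate-early genes were higher in the controls, with 6 lower and 3 higher of 14 listed in edgeR (median log2 fold change -1.19). A few libraries with high levels may account for it, since the mean score was 1.73 in control 2, 1.49 in control 3 and 0.75 in control 5, against at most -0.11 with beta-glucan. Above every beta-glucan library were 4 of the 8 controls, which lies between what a few libraries and what a shift of the whole group predict. In edgeR without controls 2 and 3, 1 gene rose and 0 fell (5 at an unadjusted p under 0.05; median -0.41). Handling before lysis and an effect of beta-glucan cannot be told apart here, because no value separates them.

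Of 100 splits of the 16 libraries into groups of 8 (of 6435 possible), 1 called as many genes as the real one in edgeR, the real split itself with 1882, and the highest of the others was 0 (at an unadjusted p under 0.05, 2738 and 1794). The listed genes were chosen with the real split, so these numbers do not show whether chance can be excluded.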
